A study of Mus musculus with 2 samples.

How the data were processed

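Total RNA from the tibia of 22-week-old female C57BL/6 mice was profiled on 2 Illumina mouse bead arrays, a platform on which each probe is a short oligonucleotide carried on many beads and biotin-labelled cRNA is hybridised to it. Per the labels, each array held 1 pool of RNA from 3 mice, and the RNA was extracted with Trizol, cleaned on a column, treated with DNase and amplified with a cRNA kit for this platform. One pool was Terc+/+ and the other Terc-/-, the genotype that lacks the RNA component of telomerase. Samples were grouped by the genotype label. There was 1 array per genotype, so no p-value or standard error could be computed for any gene, and the number of arrays limits the precision of every value. The pooling of 3 mice averages their levels and leaves the spread between animals unmeasured.

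The authors deposited 2 tables. The first, per its file header, holds non-normalized signal and a detection p-value for each of 45281 probes on each array. The deposited intensity is on a linear scale and was not background-subtracted, since no value lay below 88.7. The deposited detection p-value of a probe moves in steps of 1 over 936, which is the number of negative-control features those steps imply. The second deposited table holds 1 intensity per probe and array whose scale and normalization no label states. Its columns kept the rank order of the non-normalized arrays (Spearman rho of 1 on both arrays), are linear, and have sorted values that differ by at most 0.466, as values have after quantile normalization. Its target was not the mean of these 2 arrays, because the ratio of its sorted values to that mean ran from 0.898 to 1.02, and what else entered it is unknown. The column median was 130 on both arrays. The software and its version are not given in the sources used here.

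From the non-normalized intensities, the background of each array was estimated from the detection p-values and corrected with the normexp model (function nec of limma 3.58.1 in R 4.3.3, offset 16), the arrays were quantile normalized, and log2 was taken. A probe was called detected at a detection p under 0.01. Probe names came from the platform's annotation. Of the 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none here, and the probes with several or none were left out of gene counts. The Entrez identifiers of 34807 probes were found in the gene table of assembly GRCm38.p6, and no symbol changed through them. A gene was represented by the probe with the highest mean log2 value. Genes with a detected probe on at least 1 array entered the comparison, which was always Terc-/- minus Terc+/+. A gene was counted as higher or lower at a difference of 2-fold, a rule of size and not a test. Where all probes of a gene were above background on 1 array only, the fold is given as a bound, "at least N-fold", against the higher of the lowest detected signal on the other array and the gene's own value there. The 2-fold counts of gene lists take such genes by their bound, and list medians take their normalized values. The scanner files and saturation flags were not used here.

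Before the data were examined, 35 lists of genes were fixed for bone, marrow, muscle and other cell types and for pathways. For each, the median log2 difference over detected members was set among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these 2 arrays and is not a p-value for the genotype. Genes of a list are not independent of each other, and several genes belong to more than 1 list. The genes named in the text follow a rule of the same date. They are the 12 genes with the largest difference in each direction among those detected on both arrays, the 5 with the largest bound in each direction, up to 4 members of each list with the largest absolute difference, Terc and Xist. Genes named outside it are said to have been chosen after their values were seen, apart from the Y-linked genes, which were on a fixed list.

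The procedure was tested on simulated data for this comparison, with 200 of 9962 genes changed by known folds and an assumed noise SD of 0.15 log2. The changed genes were drawn only from brighter genes detected on the Terc+/+ array, so recovery of dim genes was not tested. Of the 100 genes changed 2-fold, 100% came out in the right direction and 53% at or past 2-fold. Of the 100 genes changed 4-fold, 100% came out past 2-fold. None of the 9762 unchanged genes passed 2-fold, and 5 of 100 random lists fell outside the central 95%, which is the share chance gives. The assumed noise is not a measurement of the spread between mice. Alternatives tried were no background correction, an offset of 50, scaling to a common median, cyclic loess, the deposited normalized values, 3 other detection filters, the mean of a gene's probes and 2 other size thresholds. Figures were drawn with matplotlib 3.10.9.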

Results

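Gene expression was measured in whole tibia of telomerase-deficient mice, labelled G3 Terc-/-, and of Terc+/+ controls, to find which transcripts of long bone differ when telomerase RNA is missing. The tibia holds mineralised bone, growth cartilage and marrow, and the RNA therefore came from bone cells and from blood-forming cells together. Each genotype was represented by 1 array of RNA pooled from 3 mice. The Terc+/+ array had a median raw intensity of 127 and 16640 detected probes, and the Terc-/- array a median of 138 and 15363 detected probes. Over the 14671 probes detected on both arrays, the normalized log2 values of the arrays correlated at r = 0.924 (across probes, which are not independent replicates). As there was 1 array per genotype, the differences below have no replicate check and describe these 2 pools.

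Terc itself had 1 probe, which was not above background on either array, so the array gives no check of the knockout. The probe of Tert, the catalytic subunit of telomerase, was chosen after its values were seen, and it was also below background on both arrays. Of the Y-linked genes of the fixed lists with a probe, Eif2s3y, Kdm5d and Uty were not detected on either array, and Xist, the transcript of the inactive X chromosome, was detected on both, at log2 values of 12.66 in Terc+/+ and 11.50 in Terc-/-. The labels give both pools as female. The 4 Xist probes differed by between -1.16 and -0.05.

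Red-cell, B-lymphocyte, eosinophil and bone-matrix transcripts were lower in the Terc-/- pool, and neutrophil transcripts and innate immune receptors were higher. Of 9953 genes detected on at least 1 array, 775 (7.79%) were 2-fold or more higher in Terc-/- by their normalized values and 1037 (10.4%) 2-fold or more lower, while 8141 lay within 2-fold. The median difference over all detected genes was 0.01 on the log2 scale. Counting genes above background on 1 array only by their bound, 684 genes were higher and 877 lower. With the background left in, 357 were higher and 499 lower. Among 592 genes past 2-fold that had a further detected probe, the next brightest probe differed in the same direction for 571 (96.5%). That agreement concerns the arrays and not the mice.

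**Figure D1:**
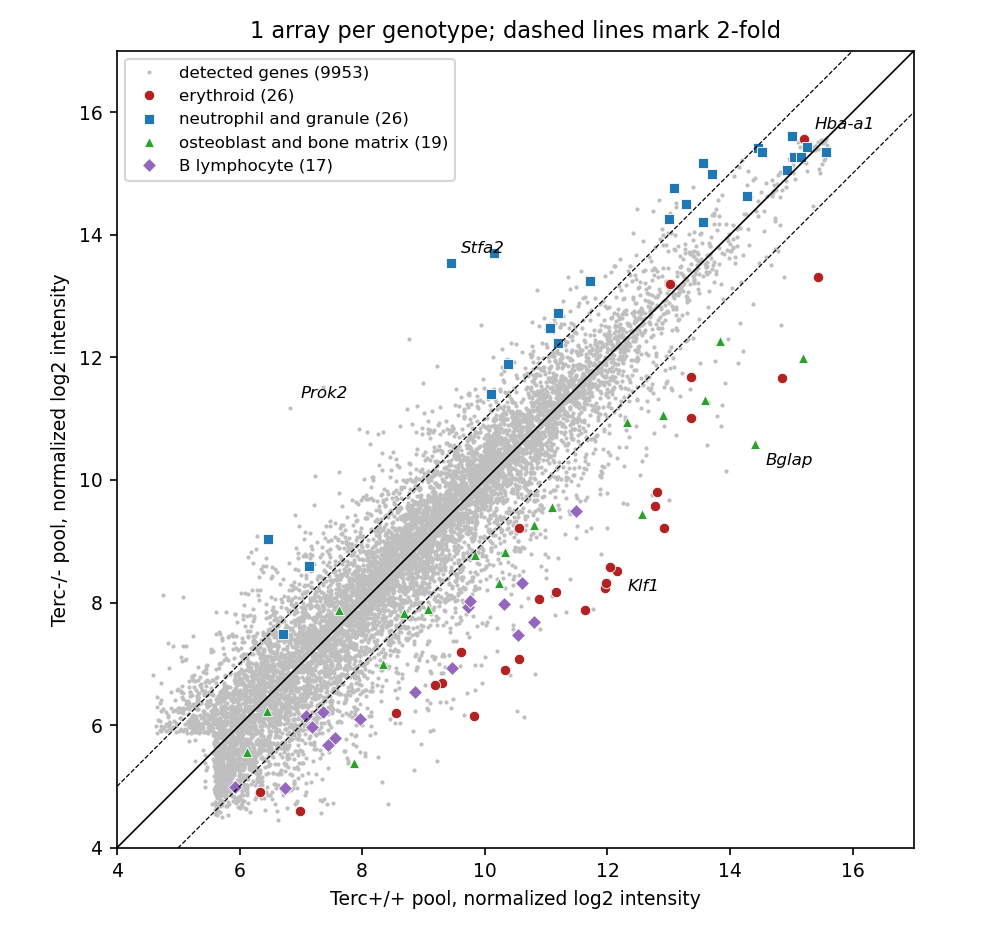
Normalized log2 intensity of each of 9953 detected genes in the Terc+/+ pool (x axis) and the Terc-/- pool (y axis), with 1 array per genotype. The solid line marks equal values and the dashed lines 2-fold; 15 of the 26 neutrophil genes lie at least 2-fold above the line of equality, and the erythroid genes, with a median difference of -2.91, lie mostly below it.

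Genes of the red-cell lineage showed the largest list median. Of 26 detected erythroid genes, 23 were at least 2-fold lower in Terc-/-, none was 2-fold higher, and the median log2 difference was -2.91, or 7.49-fold lower. Klf1, the transcription factor that drives red-cell differentiation, was 12.5-fold lower. Kel, the Kell blood group antigen, was 13.3-fold lower, Ermap, an erythroblast membrane protein, 13.5-fold lower and Trim10, a protein of terminal red-cell maturation, at -3.71. Tspo2, a membrane protein of erythroblasts, was 12.8-fold lower, and Dmtn, which bundles actin in the red-cell membrane skeleton, was 12.6-fold lower. The other detected probe of Ermap differed by -0.65 only. The brightest haemoglobin genes did not follow: Hba-a1, Hbb-bs and Hbb-bt, chosen after their values were seen, differed by 0.35, 0.09 and 0.41, and all 3 were among the 25 brightest genes, with raw intensities from 33779 to 50061. The probes of Hbb-bs and of Hbb-bt disagreed in sign, from -0.58 to 0.60 and from -1.11 to 0.41. The other erythroid list members not past 2-fold, also chosen afterwards, were Nfe2, which differed by 0.18, and Bpgm, detected in Terc+/+ only and at least 1.37-fold lower. The erythroid median lay below all 10000 random lists, and under every alternative it stayed between -3.00 and -2.40.

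Lymphoid transcripts were lower as well. Of 17 detected B-lymphocyte genes, 14 were at least 2-fold lower and none higher, with a median of -1.80. They included Vpreb3, a chaperone of the pre-B-cell receptor, at -3.11, Fcrla, an Fc-receptor-like protein of B cells, at -3.08, Pou2af1, a B-cell transcriptional coactivator, at -2.53, and Cd72, a B-cell surface regulator, at -2.34. Of 12 MHC class II presentation genes, 7 were at least 2-fold lower (median -1.40), including Cd74, the invariant chain, at -1.81 and H2-Eb1 at -1.80. This list's median was -0.69 without background correction. Of 14 T and NK genes, 6 were at least 2-fold lower and 1 higher (median -0.95), with Il7r, the interleukin-7 receptor, at -1.73, and the T-cell receptor components Cd3e and Cd3g at -1.61 and -1.57. A further probe of Cd3e was at -0.89. The exception was Nkg7, a granule protein of cytotoxic cells that is also found in early neutrophils, at 1.26, chosen after its value was seen. Of 7 plasma-cell genes, 2 were at least 2-fold lower, Mzb1 at -2.63 and Irf4 at -1.80. The plasma-cell median of -0.14 lay within the central 95% of random lists.

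Eosinophil and platelet-lineage genes were lower. Of 6 eosinophil genes, 5 were at least 2-fold lower (median -2.29, or -1.63 without background correction). They included Ear6, a ribonuclease of a family of close copies, at -4.30, Prg3 and Prg2, which encode major basic proteins of the granule, at -2.62 and -2.32, and Epx, eosinophil peroxidase, at -2.26. Of 17 megakaryocyte and platelet genes, 13 were at least 2-fold lower and none higher (median -1.27), including Gp6, the platelet collagen receptor, at -1.71, Treml1 at -1.59, and Vwf, von Willebrand factor, at -1.55. Of 11 haematopoietic progenitor genes, 3 were at least 2-fold lower, namely Gfi1b at -2.20, Tal1 at -2.08 and Slamf1 at -1.92, with a further Slamf1 probe at -0.70. The median of -0.68 lay outside the central 95% of random lists in 9 of 10 settings. Gfi1b and Tal1 are also transcription factors of the red-cell and platelet lineages. The 7 mast-cell and basophil genes had a median of -0.21, within the range of random lists, and a mean just above 0, with Hdc, histidine decarboxylase, at 1.32.

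Neutrophil transcripts were higher. Of 26 detected neutrophil and granule genes, 15 were at least 2-fold higher and none lower, with a median of 1.23, or 2.35-fold, above all random lists. Stfa2 and Stfa1, stefin A protease inhibitors of myeloid cells, were at 4.09 and 3.55 on the log2 scale and Stfa2l1 at 2.58. Their probes can cross-hybridise, since the stefin A genes are near-identical copies. Ctsg, cathepsin G of the primary granules, was 3.20-fold higher. Prok2, a chemoattractant peptide made by neutrophils, had the largest positive difference of the genes detected on both arrays, with log2 values of 6.83 in Terc+/+ and 11.17 in Terc-/-, or 20.2-fold. Cxcr1, a chemokine receptor of neutrophils, was 6.99-fold higher, Cd300lf, a myeloid inhibitory receptor, 6.09-fold higher, and Asprv1, a retroviral-like protease, 11.6-fold higher.

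Monocyte and macrophage genes went both ways. Of 22 detected members, 4 were at least 2-fold higher and 5 at least 2-fold lower, and the median of -0.09 lay inside the range of random lists. Itgam, the integrin chain CD11b of myeloid cells, was at 2.21, Cd14, the lipopolysaccharide co-receptor, at 1.73 and Fcgr3, an IgG receptor, at 1.63. Siglec1, a marker of resident macrophages, was detected in Terc+/+ only and was at least 1.86-fold lower in Terc-/-.

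Genes of innate sensing were higher. Of 19 detected toll-like receptor and sensing genes, 8 were at least 2-fold higher and none lower, with a median of 0.92, above all random lists. Clec4e, a receptor for mycobacterial glycolipid and dead cells, was at 2.08, Tirap, an adaptor of toll-like receptor signalling, at 1.67 and Tlr6 at 1.58, with a further Tlr6 probe at 0.95. Neutrophil genes were higher in the same comparison, with a list median of 1.23. Inflammatory and chemokine genes split, with 7 of 22 at least 2-fold higher and 3 at least 2-fold lower. Il1b, the cytokine interleukin-1 beta, was 6.01-fold higher, Socs3, a feedback inhibitor of cytokine signalling, 5.40-fold higher and Saa3, an acute-phase protein, 4.65-fold higher. Cxcl9, an interferon-inducible chemokine, was at -2.12. The list's median of 0.25, at the 96.2 percentile, lay inside the central 95% of random lists, was 0.62 among genes detected on both arrays, the 1 setting of 10 that put it outside, and was -0.12 at a detection p under 0.05. Of 21 interferon-response genes, 5 were at least 2-fold lower and none higher (median -0.54, percentile 0.17), led by Isg15 at -3.33, Rsad2 at -3.05, Usp18 at -1.64 and Ifit3 at -1.22.

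Transcripts of bone-forming cells were lower in Terc-/-. Of 19 detected osteoblast and bone-matrix genes, 15 were at least 2-fold lower and none 2-fold higher, with a median log2 difference of -1.52, or 2.88-fold, below all random lists. Bglap, osteocalcin, was 14.1-fold lower, and its close copy Bglap2 was 9.15-fold lower. The 2 are near-identical, so their probes can share signal. Col1a2, a chain of type I collagen, was 8.67-fold lower, and Col5a2, a chain of type V collagen, was detected in Terc+/+ only and was at least 3.96-fold lower. A further Col5a2 probe was at -0.86. The osteoblast median stayed between -1.60 and -1.34 under every alternative. Skeletal muscle and cartilage genes were also lower in this comparison, with list medians of -0.96 and -1.15. Of 7 detected osteocyte genes, 1 was at least 2-fold lower, Phex, an endopeptidase of phosphate control, at -1.95, and the median of -0.50 lay within the range of random lists. Dkk1, a Wnt inhibitor, was detected in Terc+/+ only.

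Osteoclast genes did not differ as a list. Of 15 detected members, 1 was at least 2-fold lower and none higher, with a median of 0.18 and a mean of -0.11, and the median was within the range of random lists. The 1 gene past 2-fold was Car2, carbonic anhydrase II, at -3.46, which is also on the erythroid list. Tcirg1, a subunit of the osteoclast proton pump, was at 0.84, the lowest of its 4 detected probes, which ranged up to 1.98. Src was at -0.92 and Mmp9, a protease that neutrophils also store, at 0.66. Ctsk, cathepsin K, was at -0.14 and Acp5, tartrate-resistant acid phosphatase, at -0.58, both chosen after their values were seen. Of 13 detected regulators of osteoclasts and bone-active cytokines, 3 were at least 2-fold higher, namely Il1b at 2.59, Osm, oncostatin M, at 2.08 and Tnf, which was 2.83-fold higher, and 1 was at least 2-fold lower, Il18, at -1.24. The list's median of 0.09 was within the range of random lists. Tnfsf11, the osteoclast-inducing ligand RANKL, was chosen afterwards and was at -0.23, and its decoy receptor Tnfrsf11b, osteoprotegerin, was at -0.50.

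**Figure D2:**
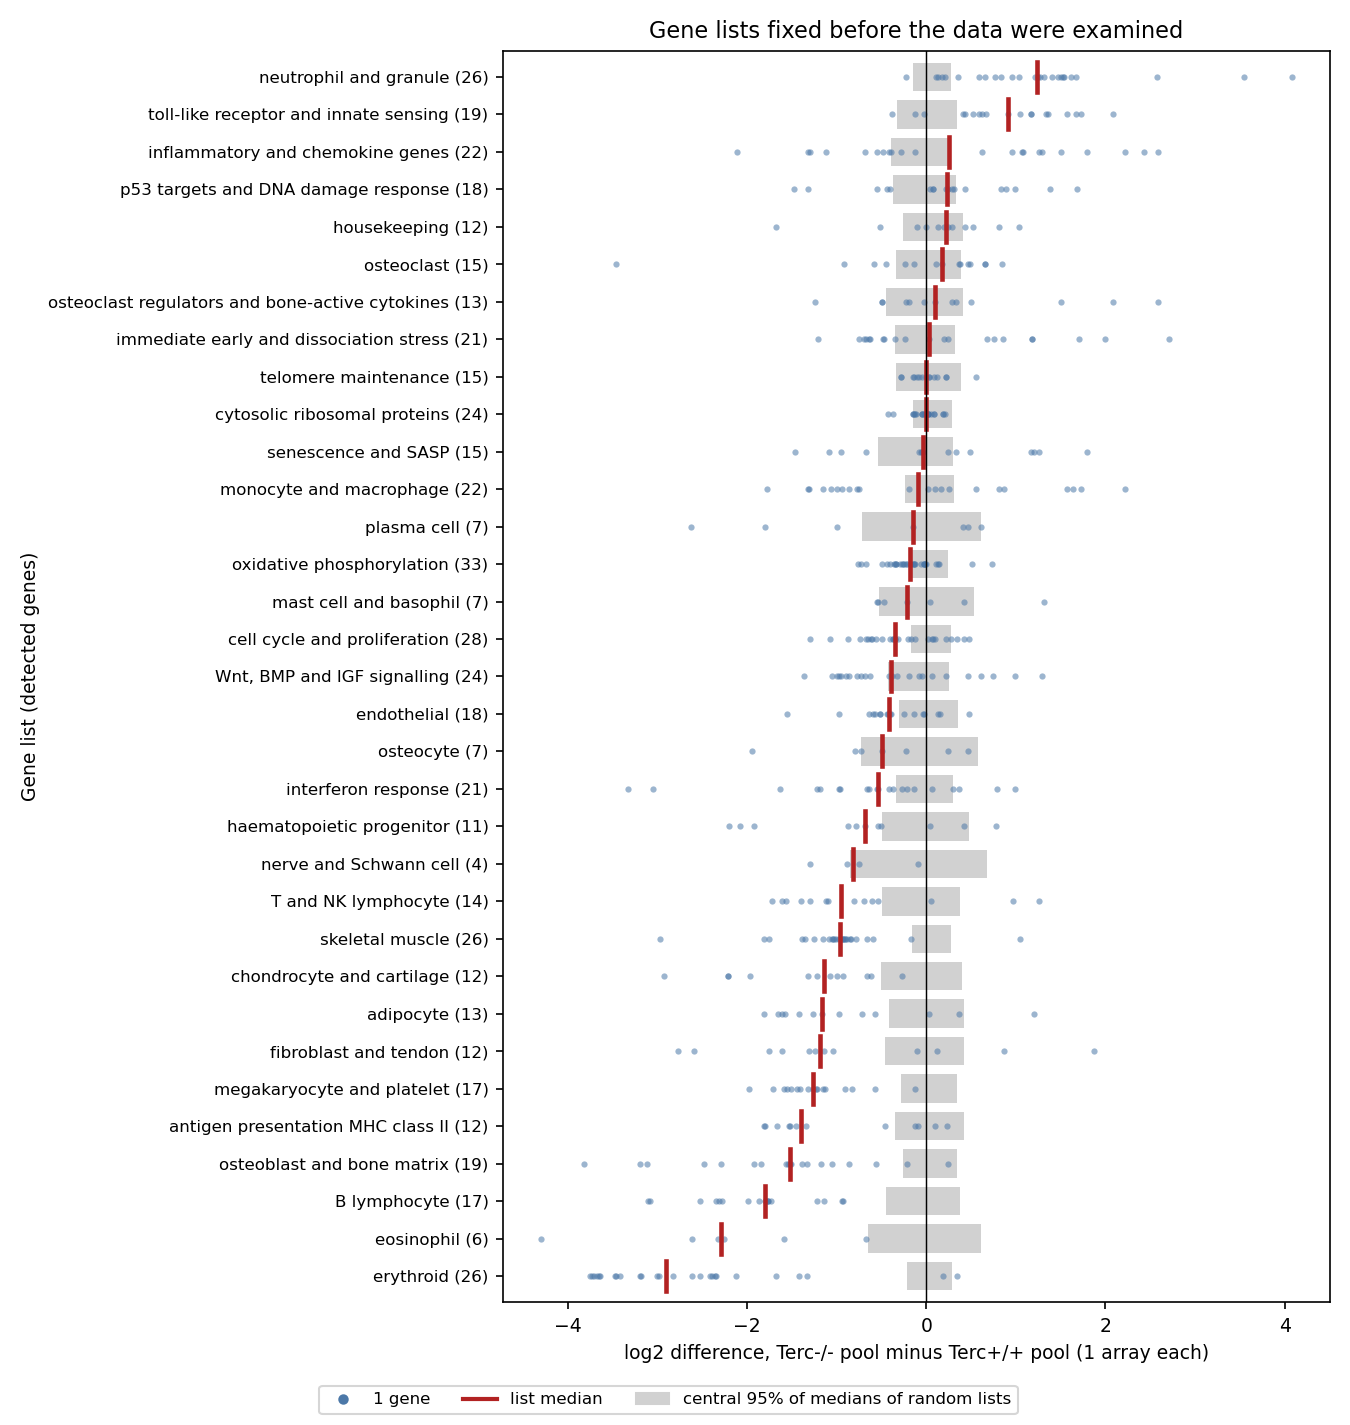
Log2 difference between the Terc-/- and the Terc+/+ pool (x axis, 1 array each) for the detected genes (points) of each of 33 gene lists (y axis, with the number of detected genes), with the list median as a red line and the central 95% of medians of 10000 expression-matched random lists as a grey bar. The erythroid median of -2.91 lies farthest to the left and the neutrophil median of 1.23 farthest to the right.

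Other tissues around and inside the bone were also lower. Of 12 detected cartilage genes, 6 were at least 2-fold lower (median -1.15), including Sox6 at -2.92, Col2a1, the main collagen of cartilage, at -2.21, and Col10a1 of hypertrophic cartilage, at least 2.29-fold lower. Sox6 is also expressed in erythroid cells. Of 12 fibroblast and tendon genes, 6 were at least 2-fold lower and 1 higher (median -1.19), with Col3a1 at -2.77, Lum, the proteoglycan lumican, at -2.59 and Pi16 at 1.88. Of 13 adipocyte genes, 7 were at least 2-fold lower and none at least 2-fold higher (median -1.17), including Adipoq, adiponectin, at -1.66, Scd1, a fatty acid desaturase, at -1.62 and Car3 at -1.81. Lipe, hormone-sensitive lipase, was detected in Terc-/- only, at least 1.91-fold higher, and was chosen after its value was seen. Without a detection filter the fibroblast median was -0.38 and the adipocyte median -0.34. Of 26 skeletal muscle genes, 12 were at least 2-fold lower and 1 higher (median -0.96), with Mb, myoglobin, at -2.97, Actn2 at -1.81 and Myh1 at -1.75. The exception was Tnnt1, of slow fibres, at 1.04, chosen afterwards. Of 18 endothelial genes, 1 was at least 2-fold lower, Vwf, and the median was -0.41. The 4 nerve and Schwann cell genes had a median of -0.82, inside the range of random lists but outside it in 2 of 10 settings, and of the skin genes only Krt10 was detected, at -0.60.

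Pathways tied to telomere loss showed smaller differences. None of 15 detected telomere-maintenance genes reached 2-fold, the largest difference was 0.55, for Ten1, and the median of -0.01 and the mean of 0.01 differed in sign. Of 18 p53-target and DNA-damage genes, 2 were at least 2-fold higher, Plk3 at 1.68 and Gadd45b at 1.38 (with a further probe at 0.53), and 2 at least 2-fold lower, Phlda3 at -1.48 and Sesn1 at -1.33. The median of 0.23 was inside the range of random lists. Cdkn1a, the cell-cycle inhibitor p21, differed by 0.24 and was chosen afterwards. Of 15 senescence and secretory-phenotype genes, 1 was at least 2-fold higher and 1 lower, with a median of -0.04 and a mean of 0.14. Plaur, the urokinase receptor, was at 1.80, while Mmp3 was above background in Terc+/+ only, at least 1.18-fold lower, and Mmp12 and Cxcl1 in Terc-/- only, at least 1.39-fold and 1.31-fold higher. Of 28 cell-cycle genes, 2 were at least 2-fold lower, Ccne1 at -1.29 and Cdc6 at -1.08, both of entry into DNA replication, and the median of -0.35 lay at the 0.08 percentile of random lists.

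Of 24 genes of Wnt, BMP and IGF signalling, 2 were at least 2-fold lower, Igf1, insulin-like growth factor 1, at -1.36 and Bmp4 at -1.06, and Id1, a BMP target, was higher at 1.30. The list's median of -0.40 was at the 3.66 percentile, inside the central 95%, and 5 of the 10 settings, alternatives included, put it outside. Oxidative phosphorylation genes differed little, with none of 33 past 2-fold and a median of -0.18 (percentile 1.62). None of 24 cytosolic ribosomal protein genes passed 2-fold (median -0.01). Of 12 housekeeping genes, Pgk1 was higher at 1.03 and Tfrc, the transferrin receptor that red-cell precursors use for iron, lower at -1.68, and the median was 0.22. Of 21 immediate early and stress genes, 4 were at least 2-fold higher and 1 lower (median 0.03), including Fos at 2.71, Junb at 1.99, Ier3 at 1.70 and Hsph1, a chaperone, at -1.21.

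Of 33 lists that could be ranked, 16 had a median below and 2 a median above the central 95% of random lists, where 1.65 would be expected outside by chance if lists were independent. The remaining genes named by size were of several kinds. The largest negative difference among genes detected on both arrays was that of Mup2, a major urinary protein from a family of near-identical copies, at -4.50, and Mup6 of the same family was at least 5.81-fold lower. Rec114 was at -3.98, Nxpe2 at -3.87 and Apol11b at -3.78, and Btnl10 was above background in Terc+/+ only and at least 10.2-fold lower in Terc-/-. Prss35, Erich2 and Agtr1a, an angiotensin receptor, were at least 7.83-fold, 8.49-fold and 5.49-fold lower. On the higher side were Cstdc5 at 4.14, a gene of the cystatin family, Dmkn at 2.87, Foxd4 at 2.83, Psmb1 at 2.64 and Dnmt3l at 2.64. The 3 probes of Dmkn ranged from 0.09 to 2.87. Csta2, Tarm1, Mfsd6l, Ambp and Slc32a1 were above background in Terc-/- only and at least 5.80-fold, 5.70-fold, 3.64-fold, 3.37-fold and 3.27-fold higher.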

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

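A list median or gene difference was taken as moved where it shifted by 1.5-fold or more, because no replicate spread exists. Of the 1812 genes past 2-fold, 1693 were also past it with scaling to a common median, 1676 with cyclic loess and 1653 with the mean of a gene's probes. Most alternatives could not turn the sign of a gene past 2-fold, so kept signs say nothing on direction. The number of genes past 2-fold did depend on the background: 357 higher and 499 lower without background correction, and 363 and 517 with the deposited normalized values. With an offset of 50 there were 510 higher and 738 lower. Background or offset left in the signal shrinks ratios. At 1.5-fold the counts were 1788 higher and 2039 lower, and at 4-fold 55 and 186. Cyclic loess moved the share of higher genes from 42.8% to 35.0%. Over all alternatives 8 list medians moved and 307 did not. Those that moved include the eosinophil and MHC class II lists (-1.63 and -0.69 without background correction) and the adipocyte and fibroblast lists without a detection filter (-0.34 and -0.38). Of the values of 157 named genes, 111 moved, none with a change of sign, and 1278 did not. Among the latter the small difference of Mbp changed sign with the mean of its probes (0.32). Medians near 0 that changed sign include those of the plasma-cell, monocyte, telomere, senescence, ribosomal and immediate early lists. No replicate could be left out, and no paired analysis was possible because each genotype had 1 array. Signal over background limits the dim genes: the lowest detected raw intensity was 150 on the Terc+/+ array and 169 on the Terc-/- array, against background medians of 108 and 120.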

Other observations

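The tests on chromosome ends, on genes beside Terc, on neutrophil stages, on further macrophage lists and on normalization were set before their results were seen. The histone values and the tests of a lower erythroid share, of dilution, of tissue preparation and of saturation were chosen after.

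Histone genes, which were on none of the fixed lists, were lower in Terc-/-. Of 51 detected genes of the H1, H2A, H2B, H3 and H4 clusters, 26 were at least 2-fold lower and none 2-fold higher, with a median of -1.27, or 2.41-fold lower. H4c6 was at -2.11, H2bc15 at -2.09, H2bc21 at -2.26 and H3c6 at -1.82. Most H2B and H4 genes were at least 2-fold lower, while most H2A genes were not. The brightest, H2ac24 and H2ac20, were at -0.03 and -0.24. Their raw intensities were in the range of the brightest haemoglobin probes, where saturation was not excluded. Dimmer genes also differed little, such as H2ac18 at 0.46, H2ac19 at -0.26 and H3c13 at 0.03. Small differences were thus not limited to the brightest genes. These genes were chosen after their values were seen. Many histone genes are near-identical copies, so their probes can share signal, which was not tested. In the same comparison the cell-cycle list had a median of -0.35 and the erythroid list, with 23 of 26 genes at least 2-fold lower, a median of -2.91.

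Erythroid genes were lower (median -2.91) and neutrophil genes higher (1.23), and 3 technical or arithmetic explanations were examined, each taken as the only cause. Under every normalization tried, the erythroid median stayed at least 2.40 below 0, and its distance from the median of all genes was never closer to 0 than -2.43. The normalizations tried thus did not remove it. They adjust each array as a whole, so they could hardly have moved 1 list so far from the other genes. A lower erythroid share alone raises every other cell type alike, but the B-lymphocyte median was -1.80. A larger neutrophil share diluting all other cells lowers them alike, but the lower quartile of the endothelial list lay 1.79 above the upper quartile of the erythroid list. The share and dilution tests were chosen after these values were seen. They go against each cause alone, and a mix of both was not tested. A change in marrow composition with genotype remains open and untested, and so does a difference between these 6 mice unrelated to genotype, since each genotype had 1 pool.

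The 3 brightest haemoglobin genes did not follow the other erythroid genes. Saturation of the brightest probes is a candidate explanation: the 30 brightest genes other than ribosomal protein genes had an SD of log2 differences of 0.377, against 0.80 over all detected genes. A dimmer probe annotated to the haemoglobin gene Hbb-b2, at rank 4505, was at -3.48 and was chosen after its value was seen. Whether that probe reads a separate gene in these mice was not tested. The files used here give no saturation flag, and bright genes can also be stable ones, so saturation and a true lack of change cannot be told apart. The same limit applies to bright genes such as S100a8 (0.21), S100a9 (0.11), Mpo (0.17, with 4 probes from 0.17 to 1.99) and Ltf (-0.23, with probes that disagree in sign), chosen after their values were seen.

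Osteoblast genes were lower (median -1.52), and the normalizations tried did not remove it, with the same limit as for the erythroid list. The distance to the median of all genes was never closer to 0 than -1.34. Less bone and attached tissue relative to marrow in the Terc-/- preparation stays open: the lists of skeletal muscle, cartilage and fibroblast genes, which are not marrow cells, were all lower, the nearest to 0 being muscle at -0.96. The osteoclast median of 0.18 and the osteocyte median of -0.50, also of cells in bone, lay within the range of random lists. The osteocyte list had 7 detected genes, 5 of them below 0, and a wide random range from -0.73 to 0.58. It therefore cannot show that osteocyte transcripts were spared. The osteoclast list holds genes of other cells too, such as Mmp9 and Car2, so it does not measure osteoclasts alone. With 1 preparation per genotype, a difference in dissection and a lower output of bone-forming cells cannot be told apart.

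Within the neutrophil lineage, a hypothesis was that the late stages alone were higher. The median of late, circulating-type genes minus that of early, primary-granule genes was -0.10, with medians of 1.31 and 1.40, so early genes were higher too. Early genes such as Elane and Mpo were already on the neutrophil list, whose values had been seen, so this was largely known beforehand. Prok2 (4.34) and Stfa2 (4.09), neutrophil genes on neither list, differed more than any gene of these lists. A shift towards late stages is therefore not excluded. Examples, chosen after their values were seen, are Gfi1 at 1.96 and Elane at 1.25 among the early genes, and Trem1 at 2.53 and Cxcr2 at 1.31 among the late ones. Early B-cell genes (median -1.83 over 4) and mature B-cell genes (-1.37 over 8) were both lower. By the bound rule, 4 of the 8 mature genes were at least 2-fold lower and none higher. All 4 early genes and several mature ones were already on the B-lymphocyte list, so this adds no separate support.

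The split of the macrophage list prompted a test on genes outside it. Of 14 detected further genes of resident macrophages, 4 were at least 2-fold lower and none 2-fold higher, with a median of -0.75. The 3 lowest were Hmox1 at -1.41, Axl at -1.31 and Spic at -1.28. Of 11 detected further monocyte genes, 5 were at least 2-fold higher and none 2-fold lower, with a median of 0.98, among them Tgfbi at 1.84 and Emilin2 at 1.11. These 5 names were chosen after their values were seen. This is consistent with fewer resident macrophages beside more or unchanged monocytes, a hypothesis from 1 pool per genotype. Resident marrow macrophages nurse erythroblasts, and the erythroid list was lower in the same pool, at -2.91. Some of the monocyte genes are also expressed by neutrophils. Whether other cells contributed to the resident list was not tested, and the fibroblast and tendon list was also lower, at -1.19.

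Short telomeres prompted a test of genes at chromosome ends, using the gene order of GRCm38.p6. The 10 distal detected genes of each of 20 chromosomes had a median of 0.04, at the 74.1 percentile of random sets, and the 10 proximal genes a median of 0.02, at the 61.3 percentile, so neither set stood apart. The lowest value of the proximal set, -3.48, equalled in all digits that of Hbb-b2, a gene of the beta-globin cluster, which does not lie at a chromosome end. The proximal set therefore appears to hold a gene from elsewhere. Both sets may hold others, which limits this test. The 10 detected genes on each side of Terc had a median absolute difference of 0.46, at the 58.0 percentile, and as a set they did not stand out. Of these 20 genes, 9 were histone genes, of which 3 were at least 2-fold lower, against 23 of 42 histone genes elsewhere. Most H2A genes lay within 2-fold in both places, and they made up a larger part of the histone genes beside Terc. The contrast therefore cannot separate position from histone class.

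Of 2490 detected probes with no gene name here, 168 were 2-fold or more higher in Terc-/- by their normalized values and 327 were 2-fold or more lower.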
